A study of Homo sapiens with 6 samples.

How the data were processed

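RNA-seq was performed on Huh7 cells, a human hepatocellular carcinoma line, that carried either a control shRNA (shCtrl) or shRNAs against KAT7 (shKAT7). Per the labels' protocols, the cells were grown in DMEM with 10% fetal bovine serum at 37 °C and 5% CO2. Per the same protocols, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit. The labels gave 6 samples in 2 groups, 3 shCtrl and 3 shKAT7, and numbered the replicates of each group from 1. No label says whether the replicates came from separate cultures.

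Per the submitters' processing notes, fastp, HISAT and HTSeq were used, and the genome build named there is mm10, a mouse assembly. Tool versions, the role of each tool and the gene annotation are not given in the sources used here. The authors deposited a table whose name says raw gene counts and a table whose name says FPKM. Each had 1 identifier column and 6 value columns, named with the letter A or B and a replicate-like number.

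None of these column names occurred in any title, description, characteristic or protocol of the samples. No label says which letter is the control. The full text of the submitters' processing notes was not among the sources read here, so a key given there would have been missed. Assigning columns by their order, or by the level of the targeted gene, would be a guess about the groups, and the second would make the knockdown its own evidence. For this reason no column was assigned to a group, and the 12 value columns of the 2 tables were not used in any step. The tests planned before the data were examined, namely edgeR's quasi-likelihood test of shKAT7 against shCtrl and camera tests of 33 fixed gene lists, were not run. A planned description of correlations between libraries and of principal components, without a test, was not made either. Neither that description nor depth per column needs a group key, and both were left out by choice. No depth, fold change, error or p-value is reported.

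The identifier columns were read with Python 3.11.15 and compared between the tables. Identifiers were matched exactly, including letter case, to current and older human symbols in a RefSeq gene table for GRCh38.p14, a table of Ensembl gene names and GENCODE release 29. Gene positions are from GENCODE release 29 (GRCh38), counted from 1, and are not coordinates from the authors' files. Members of the gene lists were matched by the symbols fixed for them. In an alternative chosen after seeing the data, they were also matched by older symbols, RefSeq synonyms and the RefSeq and Ensembl symbols of the same gene. For mitochondrial genes, RefSeq synonyms that begin with MT linked the RefSeq symbol to the fixed name. A name that is another gene's current symbol was not taken.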

Results

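Huh7 hepatocellular carcinoma cells with and without knockdown of KAT7, a histone acetyltransferase of the MYST family, were profiled by RNA-seq to compare their gene expression. The design had 3 shCtrl and 3 shKAT7 samples, and the comparison it implies is shKAT7 against shCtrl. That comparison was not made here, because the value columns of both expression tables carry names that match no sample label. Whether any gene, including KAT7 itself, was higher or lower in the knockdown is therefore not reported. The series title names the Y-box protein YBX1 and nucleotide metabolism, and neither was compared between the groups for the same reason. A comparison of the lettered columns without a direction was left out by choice, since no label says that the letters mark these groups.

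The identifier columns of the 2 tables describe which genes were listed. Each table had 25369 gene rows, with 0 repeated identifiers, and the identifier was the same in both tables for all 25369 rows. A current RefSeq human symbol was matched by 23939 rows (94.4%), and any current or older human symbol by 24234 rows (95.5%). Of the 1135 rows with no match, 1131 had LOC names, the placeholder form given to genes without a symbol. A LOC name still current in RefSeq counted as a match. Among the rows with a current RefSeq symbol, 16997 (71.0%) were protein-coding genes and 6918 (28.9%) were long non-coding RNA genes. None of the rows (0 of 25369) was written in the capital-then-lower-case form of mouse gene symbols. Of the 257 rows with any lower-case letter, 254 were human open reading frame names. The identifiers followed human naming, whereas the build in the submitters' processing notes is the mouse assembly mm10. The 254 human open reading frame names and 6918 human long non-coding RNA genes argue against a mouse annotation of the rows. Which assembly the reads were aligned to was not tested.

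KAT7 had a row in both tables. In GENCODE release 29 (GRCh38) it is a protein-coding gene on chromosome 17, from 49788555 to 49835030 on the plus strand. All 10 members of the KAT7 acetyltransferase complex list had a row, including the scaffold genes BRPF1, BRD1 and JADE1 and the accessory subunits ING4, ING5 and MEAF6. YBX1, a DNA- and RNA-binding protein gene on chromosome 1 from 42682427 to 42702349 on the plus strand, was listed with the other members of the 3-gene Y-box list, YBX2 and YBX3.

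The lists drawn up for nucleotide metabolism had a row for each of their members, and they are a selection of its genes. Such coverage was common and not particular to this theme. Of the 33 lists, 28 were complete, among them the 12 markers of leukocytes and endothelium. All 13 listed genes of de novo purine synthesis had a row, among them PPAT, which catalyses the committed step, and IMPDH2, which leads to guanine nucleotides. All 11 listed genes of de novo pyrimidine synthesis had a row, among them CAD, DHODH and UMPS. The 10 listed genes of deoxynucleotide supply, which include the ribonucleotide reductase subunits RRM1 and RRM2, and the 22 of nucleotide salvage and breakdown were also all listed. So were the 8 listed genes of the pentose phosphate pathway and the 17 of serine and one-carbon metabolism.

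Across the 33 gene lists fixed before the data were examined, 584 of 604 memberships had a row, and 28 lists were complete. The mitochondrially encoded genes had a row for 0 of 13 members under the names fixed, such as MT-ND1 and MT-CO1, and for all 13 under their RefSeq names, such as ND1 and COX1. RIGI, an RNA sensor among the interferon-stimulated genes, was listed under its older name DDX58. With these names 598 of the 604 memberships had a row and 30 lists were complete. In the 3 incomplete lists, the members without a row under any name searched were the coagulation factor gene F9 among hepatocyte secreted proteins, THY1 among Wnt and liver progenitor markers, and KRT5, SFTPB, GATA1 and HBG1 among the 14 markers of other common cultured lines. These counts describe which genes were listed. The members without a row show that the rows leave out some human genes, at least under the names searched. Whether the rows had been filtered on expression was not tested.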

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

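For shKAT7 against shCtrl no paired analysis was possible, because no label ties the value columns or their numbers to the shCtrl and shKAT7 replicates. For the same reason that comparison was not run under any setting of normalization, filtering, test or left-out replicate. Counts that rest on the identifiers were recomputed with settings chosen after seeing the data. The count of rows with a human symbol was 24234 with current and older symbols of all reference tables, 23939 with current RefSeq symbols only, 18874 with GENCODE 29 symbols only and 24234 with letter case ignored. The count of gene list memberships with a row was 584 with the symbols as fixed and 598 with other names of the same gene added, and the gene type shares were not recomputed. The direction of any difference between the columns depends on a key that says which letter is shCtrl and which is shKAT7. The size of a difference between the letters, whichever is the control, would not depend on their order, and an unsigned comparison of the letters, paired by number or not, was left out by choice rather than being impossible, since no label says that the letters mark these groups.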
